A study of Homo sapiens with 8 samples.

How the data were processed

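Mature microRNAs (miRNAs) were measured in 8 libraries from HCT116 cells that expressed DICER as wild type (WT) or with the substitution R1855L, R821H or R1003Q, with 2 libraries per group. Groups and replicate numbers were read from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, 100 µg entered AQ-seq, a small-RNA library method with reduced ligation bias, the cDNA was amplified with NEBNext Ultra II Q5, and libraries were run on a NovaSeq. The submitters' processing notes name cutadapt, BWA and bedtools and the builds hg38 and mm10, without versions, order or roles. The miRNA annotation release, the mapping settings and the role of mm10 are not given in the sources used here.

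Each library has a deposited table of estimated counts, a read count per mature miRNA name, not normalised and not pooled. Between 19 and 33 names per library carry fractions of a read, as a read shared between several annotated places would give. A name is listed from 1 read upward, so names absent from a library were set to 0. No name lies outside the human set, so the planned scaling by spike-ins was not run. The tables give no read ends, so the planned comparison of 5-prime end positions was not run either. Mature names pool identical products of several loci, and near-identical family members (let-7, miR-320) may share reads. The reads carry no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

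Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Names were kept by filterByExpr, which left 625 of 1818, holding at least 99.85% of the reads of every library. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions was fitted to all 8 libraries. Each mutant was compared with WT, and the mutants with each other. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM (reads scaled to a common library total), given as mean ± SD over the 2 libraries of a group. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

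Strand ratios, log2 of 5p reads over 3p reads with a pseudocount of 0.5 on each, were tested with limma 3.58.1 in 174 miRNA pairs with at least 80 reads per strand over the 8 libraries. The variance prior followed the mean log reads of the pair and was robust. A total of 14 miRNA lists were fixed, 13 of which had at least 2 tested members and were tested with camera (preset correlation of 0.01, and again with an estimated correlation) and fry, with adjustment over lists. Hairpin positions were taken from GENCODE release 29 (GRCh38) by name, and 623 of the 625 tested names (99.7%) matched. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

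The tests, the lists, the alternatives listed below except where noted and the rule for named miRNAs were set before the data were examined. The rule takes, per mutant against WT, the 10 largest and 10 smallest log2 fold changes among called miRNAs with a mean of at least 50 CPM over the groups compared and with both mutant libraries on the same side of both WT libraries. It takes 5 and 5 for comparisons between mutants and for strand ratios, the 10 most abundant miRNAs in WT, and list members that were called or most abundant in WT. Alternatives were DESeq2 1.42.0, median-ratio size factors, total counts without a composition factor, no filter, a stricter filter of 50 CPM, only the 4 libraries compared, the replicate number as a block, each library left out, another pseudocount (5) and read minimum (400), and the estimated correlation. A depth term and a log2 library total covariate were added after seeing the data. Deep and shallow libraries were separated at the widest gap between library totals on the log scale, which put WT replicate 2, R1855L replicate 1 and R821H replicate 1 on the deep side and the other 5 on the shallow side.

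The counting test was tested on simulated data drawn from the observed means, library sizes and trended dispersions, with 200 of 625 miRNAs changed. In all simulations miRNAs were drawn independently with the same dispersion in every group, and only those of the depth term held a depth difference. The spread of the real libraries differed between groups, so the false-call counts need not hold for them. In the simulation of R1855L against WT, 25% of 2-fold and 85% of 4-fold changes were recovered, with 4 false calls among 114. For R821H the shares were 24% and 83% with 8 false calls among 115, and for R1003Q they were 22% and 77% with 5 among 104. The strand test recovered 60.9%, 53.2% and 59.1% of ratio changes of 4-fold or more in the simulations of R1855L, R821H and R1003Q, with 0, 3 and 0 false calls among 29, 31 and 29. With the depth term, 80%, 73% and 65% of 2-fold and 96%, 98% and 93% of 4-fold changes were recovered, with 3, 5 and 8 false calls among 179, 176 and 166. Those data were simulated with the depth differences and dispersions that the depth-term fit itself had estimated.

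Same-group libraries were compared before averaging: the chi-square per degree of freedom was 238 in WT, 227 in R1855L, 122 in R821H and 13.0 in R1003Q, all far above the sampling noise. The fits to all 8 libraries share the spread across groups. The R1003Q pair, with the lowest value, enters that spread, so p-values for R1855L against WT may be too small.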

Results

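DICER is the RNase III enzyme that cuts precursor hairpins into miRNA duplexes with a 5p and a 3p strand. miRNAs were counted in HCT116, a human colorectal carcinoma cell line, rescued with WT DICER or with R1855L, R821H or R1003Q DICER. The comparisons ask how each substitution changes the miRNA population relative to WT, and whether the substitutions differ from each other. Library totals were 1137858 and 4269231 reads in WT, 2241881 and 462805 in R1855L, 3340304 and 841857 in R821H, and 1143373 and 675934 in R1003Q (replicates 1 and 2). A count of 0 allows 3 reads, which is 0.703 CPM in the deepest library and 6.48 CPM in the shallowest. miR-21-5p, a miRNA abundant in many carcinomas, took between 28.8% of reads (exact Clopper-Pearson 95% interval 28.7 to 28.9, WT replicate 1) and 45.2% (45.1 to 45.2, R1855L replicate 1).

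The composition of the libraries differed with their depth. With group in the model, 228 of 625 miRNAs differed between the deep and the shallow libraries, 111 higher and 117 lower in the deep ones (edgeR, adjusted). This difference rests on WT, R1855L and R821H, since the R1003Q libraries are of 1 class and add only to the spread. The 9 tested let-7 miRNAs, a family of differentiation-associated tumour suppressors, had a median difference of 1.43 log2 units toward the deep libraries. The 10 tested names that overlap other non-coding RNAs had a median of -1.05, and the 5 tested capped-hairpin miRNAs a median of -1.43. WT, R1855L and R821H each had 1 deep and 1 shallow library, and both R1003Q libraries were shallow. Within each class R1855L had the lowest total, 2241881 reads among the deep and 462805 among the shallow libraries. The depth term and ratios within depth classes therefore leave a depth difference between R1855L and the other groups.

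R1855L changed the levels of 36 of 625 miRNAs against WT, 34 lower and 2 higher. miR-484 was lowest relative to WT, at 34.2 ± 19.2 CPM (SD, n = 2) against 1107 ± 96.5 CPM, a 34.5-fold lower fitted level (log2 fold change -5.11, SE 0.43, edgeR adjusted p = 0.00184). miR-331-3p fell from 795 ± 157 to 49.9 ± 21.2 CPM (log2 -3.94, SE 0.35, adjusted p = 0.00184). miR-222-3p, the second of the abundant miRNAs in WT and a repressor of the cell-cycle inhibitor p27, fell from 79310 ± 3640 to 17780 ± 1000 CPM (log2 -2.16, SE 0.26, adjusted p = 0.00513). miR-221-3p, encoded beside it and sharing its seed sequence, was at 33480 ± 3470 CPM in WT and 28420 ± 2610 CPM in R1855L, with a log2 fold change of -0.24 (SE 0.26) that did not pass the test.

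**Figure D1:**
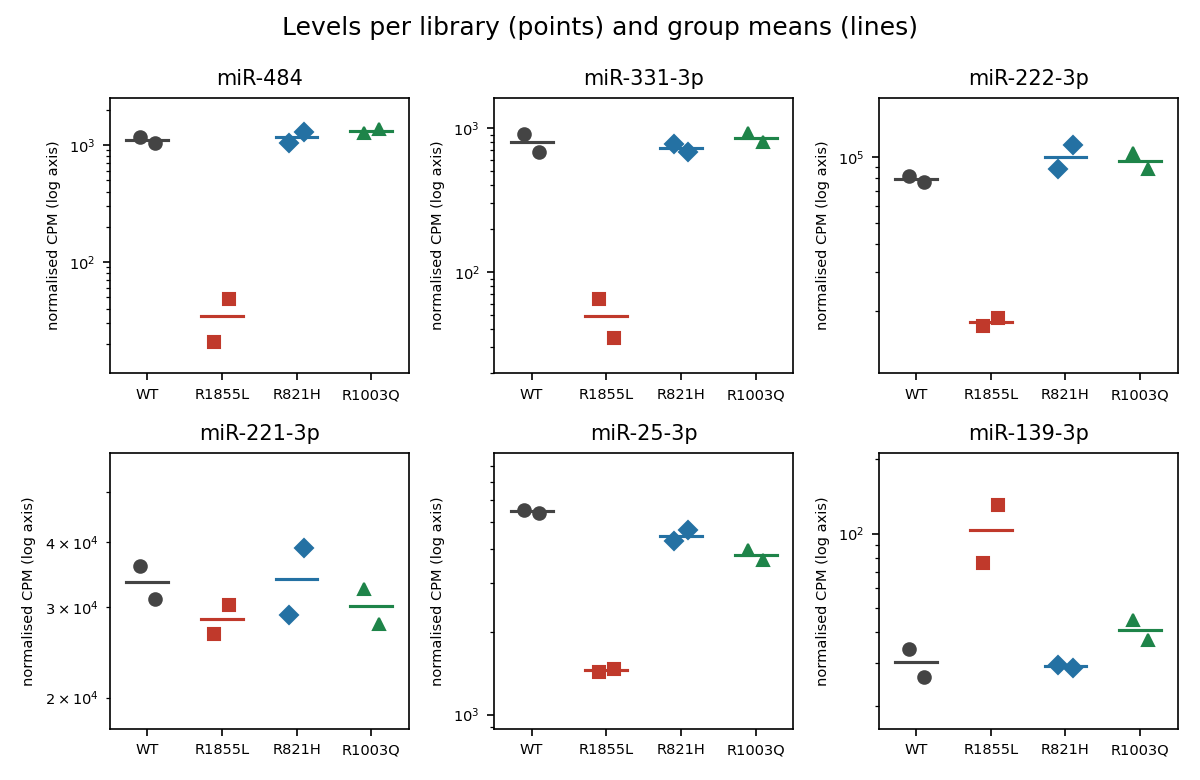
Normalised CPM (log axis, a different range in each panel) of 6 miRNAs in the 8 libraries, with points for libraries and lines for the means of 2 libraries per group. miR-484 lies at 20.6 and 47.8 CPM in the R1855L libraries and between 1039 and 1375 CPM in the others, while miR-221-3p lies at 26580 and 30270 CPM in R1855L and at 35940 and 31030 CPM in WT.

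The remaining miRNAs that the rule named fell by 1.92 to 2.82 log2 units in R1855L. They were miR-615-3p (-2.82, SE 0.49), miR-3200-3p (-2.64, SE 0.34), miR-99b-5p (-2.25, SE 0.49), miR-203b-3p (-2.25, SE 0.27), miR-1307-3p (-2.02, SE 0.30), miR-222-5p (-2.02, SE 0.31) and miR-25-3p (-1.92, SE 0.23). miR-139-3p was the only miRNA the rule named as higher, at 103 ± 38.8 against 30.2 ± 5.59 CPM (log2 1.76, SE 0.35, edgeR adjusted p = 0.0306). Within depth classes the log2 ratio of R1855L to WT was -5.62 between the deep and -4.60 between the shallow libraries for miR-484, and -2.17 and -2.15 for miR-222-3p. For miR-139-3p it was 1.51 and 1.92. In GRCh38, MIR484 lies on chromosome 16 at 15643294 to 15643372 and overlaps an exon of NDE1, and MIR331 on chromosome 12 at 95308420 to 95308513 between genes. MIR222 (X, 45747015 to 45747124) and MIR221 (X, 45746157 to 45746266) lie in an intron of MIR222HG, MIR25 (7, 100093560 to 100093643) in an intron of MCM7, and MIR139 (11, 72615063 to 72615130) in an intron of PDE2A.

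**Figure D2:**
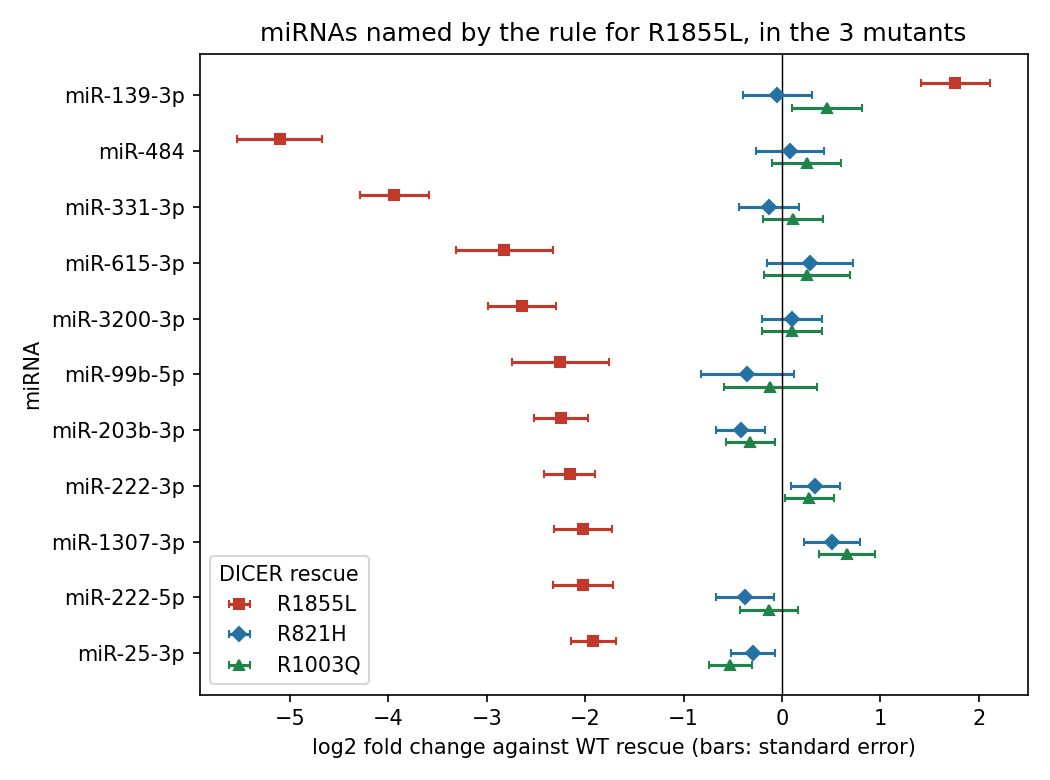
Log2 fold change against WT (horizontal axis, bars of 1 standard error, 2 libraries per group) of the 11 miRNAs named by the rule for R1855L, in the 3 mutants. The R1855L values run from -5.11 for miR-484 to 1.76 for miR-139-3p, and none of the R821H and R1003Q values passed the test.

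The count of R1855L calls depended on the model. DESeq2 called 52 (8 higher, 44 lower), a fit to only the 4 libraries compared called 2, and scaling by total counts called 14. The depth term, added after seeing the data, gave 177 calls (73 higher, 104 lower) that included all 36, and leaving out R1855L replicate 1 left 8.

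Among the 10 most abundant miRNAs of WT, miR-222-3p was the only one called in R1855L with group alone in the model. miR-21-5p, at 334700 ± 121000 CPM in WT and 373200 ± 176000 CPM in R1855L, differed by less than the replicate spread. The log2 fold changes of miR-100-5p (1.07, SE 0.33), miR-10a-5p (0.81, SE 0.25) and miR-29a-3p (-0.79, SE 0.30) did not pass adjustment in that model, whereas miR-10a-5p was called higher with the depth term. miR-31-5p, miR-27a-3p, miR-16-5p and miR-24-3p had log2 fold changes between -0.18 and 0.02.

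Listed names from Drosha-independent hairpins were lower as lists in R1855L, which does not mean that both strands of each hairpin fell. Mirtrons are short introns that splicing rather than Drosha turns into precursor hairpins. Of their 11 tested names 4 were called lower, or 5 adjusted over the list alone, and none was called higher. Their median log2 fold change was -1.22, with 3 names above 0. miR-1229-3p had 3 and 0 reads in R1855L against 29 and 69 in WT, and miR-1228-3p had 3 and 0 against 18 and 41. miR-1224-5p (log2 -2.42, SE 0.55) and miR-1226-3p (-2.89, SE 0.66) also fell, and the most abundant mirtron, miR-877-5p, had -1.06 (SE 0.25), called over the list alone. By contrast, miR-1226-5p had 44 and 10 reads in R1855L against 40 and 68 in WT. The miR-1226 strand ratio changed by 2.36 toward 5p (SE 0.63, limma adjusted p = 0.0515). The capped-hairpin list holds miR-320 and miR-484, whose precursors form from transcript 5-prime ends. Of its 5 tested members 1 fell, or 2 over the list alone (miR-484 and miR-320a, the latter -1.31, SE 0.39), and the median was -1.26. Both lists passed camera (adjusted p = 0.00322 and 0.00046), and neither did with an estimated correlation (adjusted p = 0.749 and 0.361). Without R1855L replicate 1 the mirtron list had an adjusted p of 0.0927 by camera, and with the depth term 6 of 11 mirtrons and 5 of 5 capped-hairpin miRNAs were called lower.

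Names derived from snoRNAs and names overlapping other non-coding RNAs, whose reads may include fragments of those RNAs, were higher as lists in R1855L. Their medians were 0.86 over 11 names and 0.91 over 10 names, with no single member called over all miRNAs or over the list alone. Camera gave an adjusted p of 0.038 for each, and with an estimated correlation the adjusted p was 0.361 and 0.749. The list overlapping other non-coding RNAs also moved with depth (-1.05 in the deep libraries), and its median was -0.01 without R1855L replicate 2. With the depth term 4 of 11 snoRNA-derived names and 6 of 10 of the other list were called higher, with medians of 0.90 and 1.01 (camera adjusted p = 0.0272 and 0.00164). With an estimated correlation the camera p under that model was 0.0773 and 0.0311. R1855L had the lowest total in each depth class, so the rise of the list overlapping other non-coding RNAs was not separated from depth.

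Of the 5 tested members of the miR-200 family, epithelial miRNAs that repress ZEB transcription factors, miR-429 (-1.04, SE 0.21) and miR-141-3p (-1.39, SE 0.30) fell in R1855L, also over the list alone, and the other 3 were not called. The family as a list did not pass camera (adjusted p = 0.392). Among the 11 tested members of the miR-17-92 family and its paralogs, a growth-promoting group, miR-25-3p fell and no other member was called, with the same count over the list alone, and the list did not pass camera. miR-92a-3p, the most abundant of that list, had a log2 fold change of 0.61 (SE 0.28), and was called higher with the depth term (0.59, SE 0.16). The let-7 family had a median of -0.60 with 0 of 9 called, over all miRNAs or over the list alone (camera adjusted p = 0.392). With the depth term 6 of its 9 members were called lower in R1855L, with a median of -0.68 (camera adjusted p = 0.0118), and the camera p was 0.319 with an estimated correlation. The let-7 miRNAs were higher in deep libraries and R1855L had the lowest total in each depth class. This fall was thus not separated from the depth difference that the term leaves. None of the 7 tested miRNAs induced by p53 was called without the depth term, where miR-34a-5p had -0.56 (SE 0.33). With it, miR-34a-5p (-0.58, SE 0.18) and miR-107 (-0.75, SE 0.19) were called lower. miR-451a, whose hairpin matures without DICER, had 0.25 (SE 0.47).

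With group alone in the model, no list passed the directional test of fry in any mutant (smallest adjusted p = 0.0688, for capped hairpins and snoRNA-derived names in R1855L). In R1855L mirtrons had an adjusted p of 0.136 by that test, and in R821H and R1003Q the let-7 family had 0.836 and 0.582. The mixed test of fry, which counts changes in either direction, passed in R1855L for the miR-200 family (adjusted p = 0.000289), capped hairpins (0.00115), the miR-17-92 family (0.0109) and mirtrons (0.0118), and for no list in R821H or R1003Q.

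Listed marker miRNAs of other cells showed no called member in any mutant without the depth term, and with it miR-10a-5p, on the HEK293 list, was called higher in R1855L (0.80, SE 0.17). miR-10a-5p is among the 10 most abundant miRNAs of WT here (12710 CPM), so it does not mark other cells in these libraries. In R1855L the camera adjusted p was 0.632 for 5 blood miRNAs and 0.736 for 4 miRNAs of HEK293 cells, and 6 muscle, liver and neuron miRNAs did not pass either. Read counts within the blood list varied. miR-223-3p, a myeloid miRNA, had between 2 and 9 reads per library, miR-150-5p 2 to 10 and miR-155-5p 0 or 1. By contrast, miR-142-3p had 208 to 1284, miR-451a 78 to 978, miR-486-5p 34 to 258.5, miR-142-5p 38 to 244 and miR-144-3p 17 to 80. Comparisons of mutants with WT do not show whether other cells were present in every library.

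The strands of a hairpin moved unequally in R1855L. Of 243 tested 3p strands 21 fell, against 8 of 268 tested 5p strands (odds ratio 3.07, two-sided Fisher's exact p = 0.00685). That test takes miRNAs of the same libraries as independent, so its p does not measure the spread between libraries. Median log2 fold changes were -0.06 for 3p and 0.22 for 5p strands, and 5p strands were higher as a list, with a camera p of 0.0125 at the preset correlation. The 3p strands were lower as a list in all 3 mutants, with a camera p of 0.00186 in R1855L, 0.0289 in R821H and 0.00431 in R1003Q. Their median log2 fold changes were close to 0 in R821H (-0.05) and R1003Q (-0.02). All 3 comparisons use the same WT libraries, so they are not independent of each other. The 5p list did not pass in R821H (median 0.09, camera p of 0.325) or R1003Q (median 0.07, camera p of 0.359). With an estimated correlation the camera p was 0.141 for the 5p list in R1855L, and 0.164, 0.242 and 0.151 for the 3p list in R1855L, R821H and R1003Q. Without R1855L replicate 1 the 3p list no longer passed in R1855L (camera p of 0.143) and the difference of the medians was 0.0194, and without either WT or either R821H library it did not pass in R821H (camera p from 0.0524 to 0.127). The 5p list turned its camera direction without WT replicate 1 in R821H and R1003Q.

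The 5p to 3p ratio within hairpins, which library scaling cannot move, changed in 13 of 174 pairs, 10 toward 5p and 3 toward 3p. The miR-331 log2 ratio went from -1.67 ± 0.38 (SD, n = 2) to 2.53 ± 0.46, a change of 4.20 (SE 0.37, limma adjusted p = 0.000209). The miR-25 ratio changed by 2.77 (SE 0.34), that of miR-203b by 2.77 (SE 0.58) and that of miR-27b by 1.95 (SE 0.35). The largest fitted change, in miR-6765, rested on a 3p strand with 1 and 0 reads in R1855L against 15 and 50 in WT. Toward 3p, the ratio of miR-185 changed by -2.89 (SE 0.38), that of miR-139 by -1.82 (SE 0.37) and that of miR-99b by -1.56 (SE 0.35). All 8 had the same sign between the deep and between the shallow libraries. This follows from both R1855L libraries lying on one side of both WT libraries in each of the 8. The depth term gave 32 called ratios, 25 toward 5p and 7 toward 3p, a fit to only the 4 libraries gave 4, and leaving out WT replicate 1 gave 4.

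**Figure D3:**
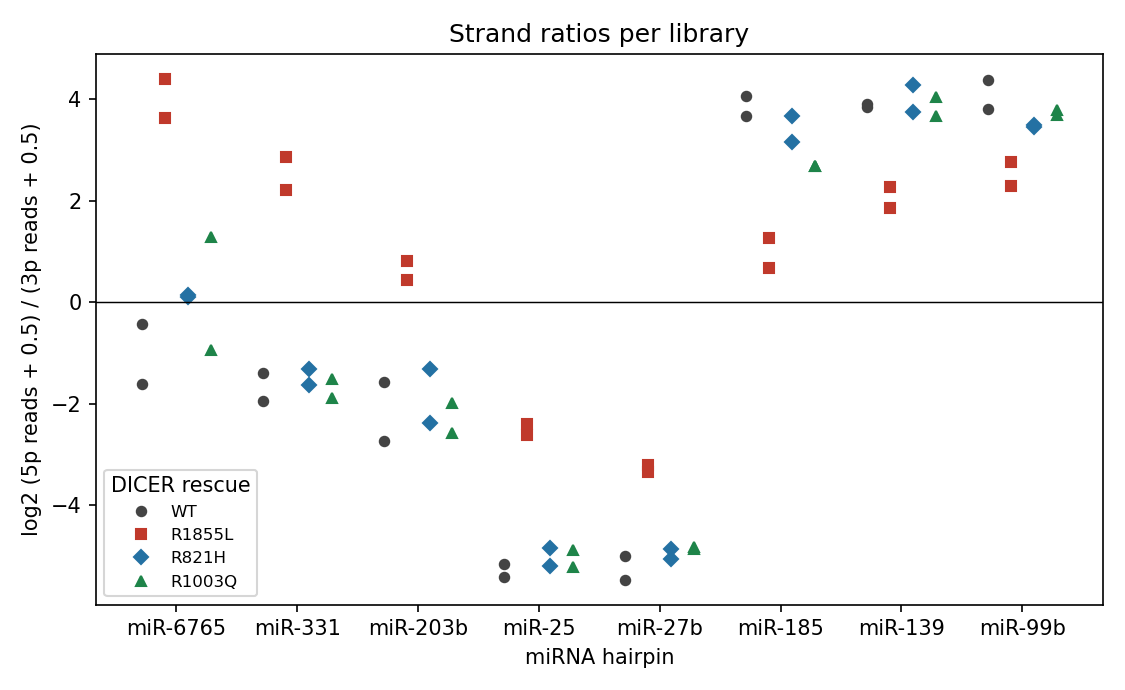
Log2 ratio of 5p to 3p reads (vertical axis, pseudocount of 0.5 on each strand) for the 8 hairpins named by the rule, with 1 point per library. The R1855L libraries stand apart from the other 6 for each hairpin, for example at 2.21 and 2.86 for miR-331 against values from -1.94 to -1.32.

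R821H and R1003Q gave no called miRNA against WT by edgeR with group alone in the model, and 16 and 2 with the depth term. For R821H, edgeR called 0 of 625, with 20 at an unadjusted p under 0.05. DESeq2 called 1, miR-185-5p at -1.03 (SE 0.23), named after its value was seen. For R1003Q, edgeR called 0, with 31 at an unadjusted p under 0.05, and DESeq2 called 0. At this depth and spread most 2-fold changes would have been missed, since 24% and 22% of those simulated were recovered. With the depth term the shares were 73% and 65%, in data simulated with the depth differences and dispersions of that same fit. They hold only if the depth split is the true structure. The most abundant miRNAs had small fitted changes: miR-21-5p had 0.24 (SE 0.41) in R821H and -0.02 (SE 0.41) in R1003Q, and miR-222-3p had 0.34 (SE 0.25) and 0.28 (SE 0.25). No strand ratio was called by limma in either mutant with group alone in the model, with 3 and 8 of 174 at an unadjusted p under 0.05. With the depth term 1 was called in R1003Q, that of miR-590 (1.25, SE 0.32, limma adjusted p = 0.021), and 0 in R821H.

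The let-7 family was lower as a list in both mutants by camera. Its median was -0.81 in R821H (adjusted p = 0.0324) and -1.14 in R1003Q (adjusted p = 0.000271), with 7 of 9 and 8 of 9 members below 0 and no member called over all miRNAs or over the list alone. With an estimated correlation the family had adjusted p = 0.791 in R821H and 0.774 in R1003Q. The 6 members of let7 group II, whose precursors carry a 1-nucleotide overhang, had medians of -0.82 and -1.26 (adjusted p = 0.0324 and 0.000271), with adjusted p = 0.791 and 0.774 under an estimated correlation. Group I, let-7c-5p and let-7e-5p, did not pass as a list in any mutant (adjusted p = 0.833 in R821H and 0.763 in R1003Q), and let-7a-5p is in neither group. The let-7 miRNAs also moved with depth, and without WT replicate 2, the deepest library, the family medians were 0.01 in R821H (adjusted p = 0.910) and -0.30 in R1003Q (adjusted p = 0.370). With the depth term they were -0.59 and -0.15 (camera adjusted p = 3.02e-05 and 0.0165), with 2 and 1 members called lower, and with an estimated correlation the camera p was 0.164 and 0.318.

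**Figure D4:**
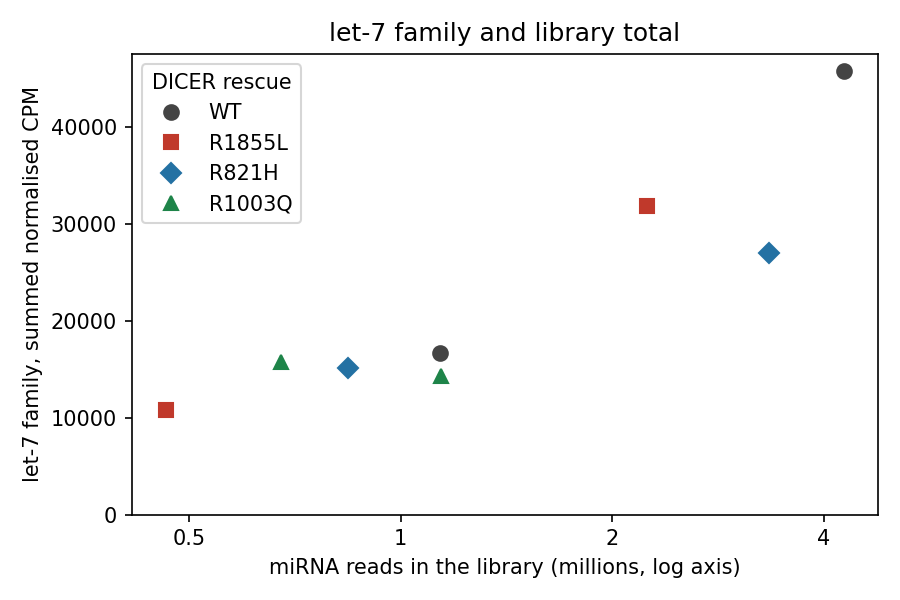
Summed normalised CPM of the 9 tested let-7 family members (vertical axis) against the miRNA reads of the library (log axis), with 1 point per library. The 3 deep libraries hold 27040 to 45809 CPM and the 5 shallow libraries 10765 to 16706 CPM.

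With the depth term, 16 miRNAs were called in R821H (5 higher, 11 lower) and 2 in R1003Q, both lower. The R1003Q pair, miR-98-5p (-1.17, SE 0.24, edgeR adjusted p = 0.0173) and miR-98-3p (-1.40, SE 0.30, adjusted p = 0.0173), was chosen after its values were seen and comes from the hairpin MIR98 in an intron of HUWE1. Both were also called lower in R821H, at -1.46 (SE 0.22) and -0.98 (SE 0.24). miR-98-5p belongs to the let-7 family and to group II, and is the only member called in R1003Q, while let-7d-5p (-0.81, SE 0.18) was called beside it in R821H. The capped-hairpin list, the list overlapping other non-coding RNAs and the snoRNA-derived list were higher in R821H with the depth term. Medians were 0.67, 0.41 and 0.49 (camera adjusted p = 0.00952, 0.0113 and 0.0118), with 0 of 5, 1 of 10 and 1 of 11 names called higher. With an estimated correlation the camera p was 0.193, 0.0549 and 0.0583.

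Without the depth term, the snoRNA list was higher in R821H (median 0.50, camera adjusted p = 0.0294, 0 of 11 called over all miRNAs or the list alone) with adjusted p = 0.422 under an estimated correlation. Of the fixed lists, none other than this and the let-7 lists passed in R821H and R1003Q with all 8 libraries and no depth term, and mirtrons had medians of -0.15 and 0.02 and capped hairpins 0.91 and 0.50.

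Direct comparisons between mutants set R1855L apart. Against R1855L, 24 miRNAs differed in R821H (22 higher, 2 lower) and 23 in R1003Q (all higher). miR-484 was higher by 5.19 (SE 0.43, edgeR adjusted p = 0.00226) in R821H and 5.36 (SE 0.44, adjusted p = 0.00157) in R1003Q. The corresponding values were 3.81 and 4.06 for miR-331-3p, 3.11 and 3.08 for miR-615-3p, 2.74 in each for miR-3200-3p, and 2.53 and 2.68 for miR-1307-3p. Lower in R821H than in R1855L were miR-139-3p (-1.81, SE 0.36) and miR-185-3p (-1.77, SE 0.34). Leaving out R821H replicate 2 left 2 calls, and leaving out R1003Q replicate 1 left 2. R1003Q and R821H did not differ in any miRNA by edgeR (10 at an unadjusted p under 0.05) or by DESeq2 (0), nor in any strand ratio by limma (2 at an unadjusted p under 0.05).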

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

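The tests of the shallowest library, of scaling, of the deep libraries, of sampling depth and of the depth split were chosen after the results they bear on were seen, and the tests of hairpin GC content before. Direct tests between mutants found 24 miRNAs that differed between R821H and R1855L and 23 between R1003Q and R1855L, so that the effects relative to WT differ between these mutants. Strand ratios differed in 11 pairs between R821H and R1855L and in 13 between R1003Q and R1855L.

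Mirtrons and capped-hairpin miRNAs were lower in R1855L, with a median log2 fold change of -1.24 over their 16 tested names. Their hairpins are GC-rich (median 64.0% against 52.2%), and of 10000 lists matched on hairpin GC content and abundance 0.01% had a median as low. Those lists drew miRNAs independently and without regard to strand, whereas the listed names are correlated (camera estimates of 0.429 and 0.295). The share is therefore likely too small and does not decide on GC content. Across miRNAs, Spearman's rho of R1855L log2 fold change and hairpin GC content was -0.054. The shallowest R1855L library alone does not account for the pattern, since the median was -1.70 between the deep libraries, with 14 of 16 below 0. A biological explanation was not tested, since cleavage of the hairpins was not analysed here. Shared reads within the miR-320 family were not tested, and the lists were not called with an estimated correlation (adjusted p = 0.749 and 0.361).

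3p strands were lower than 5p strands in R1855L. Scaling cannot produce the 10 within-hairpin ratios that limma called toward 5p, against 3 toward 3p. For the balance the exact binomial p was 0.0923, and 0.00210 for the calls with the depth term. The binomial test takes hairpins measured in the same libraries as independent. In all 10 both R1855L libraries lay above both WT libraries, so their change above 0 in both depth classes is no further support. The median over all 174 pairs was 0.229 log2 units toward 5p, but 0.0215 without R1855L replicate 1 and 0.455 without replicate 2. That shift may belong mostly to the deep libraries, where its median was 0.390, against 0.0784 between the shallow ones. A biological effect of R1855L on the median stays open and was not separated from the depth split.

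Library composition followed depth, let-7 included. Fewer reads alone do not shift a mean level, whereas edgeR called 228 of 625 miRNAs between the deep and shallow libraries of the same groups. Across 623 miRNAs the depth difference fell with hairpin GC content (Spearman's rho -0.544; miRNAs are not independent replicates), which is consistent with a GC-dependent step such as amplification, though it does not identify one. The median let-7 change in R1003Q went from -1.14 to -0.149 with the depth term, while camera still called the family (adjusted p = 0.0165; p = 0.318 with an estimated correlation). Most of the family difference thus went with the depth term, miR-98-5p was called in R1003Q only once that term was added (-1.17), and whether the rest of the family keeps a difference stays open.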

How the results depend on the processing

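The depth term, the log2 total covariate and the left-out libraries for the 3p list were chosen after seeing the data; the other alternatives were planned. All 36, 24 and 23 miRNAs called in R1855L against WT, R821H against R1855L and R1003Q against R1855L were called with the same sign with DESeq2, median-ratio size factors and either depth model. Calls in these comparisons numbered 14, 8 and 11 with total counts only, 2, 6 and 10 with only the 4 libraries compared, 177, 114 and 93 with the depth term, and 162, 86 and 81 with the log2 total. DESeq2 gave 52, 39 and 40, and no filter 53, 40 and 32. In R821H against WT, DESeq2 called 1, the depth term 16 and the log2 total 4 (let-7i-3p, miR-185-5p, miR-374b-5p and miR-6886-5p); in R1003Q the depth term called 2. Total counts moved the median of all miRNAs in R821H from 0.04 to -0.08.

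The replicate block gave 19, 15 and 13 calls, all among those of the unblocked fit. Replicate numbers did not pair the libraries: replicate 1 deviations correlated at -0.701 between WT and R1855L, -0.685 between WT and R821H and 0.569 between R1855L and R821H. The depth term sets WT replicate 2 with R1855L replicate 1 and R821H replicate 1. Of 15 other splits tried as a term, 1 differs only in the side of R1003Q, which is the same model, so it had to give the same 177. Splits that kept this arrangement but divided the R1003Q pair gave 57 and 68, and the others gave 19 to 25.

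With 1 library left out, calls ranged from 8 to 26 in R1855L against WT, 2 to 22 in R821H against R1855L and 2 to 20 in R1003Q against R1855L; the lone library is assumed to vary like the others. The difference of 5p and 3p medians ranged from 0.0194 to 0.516 in R1855L, 0.0256 to 0.195 in R821H and 0.0247 to 0.165 in R1003Q. The camera direction reversed without WT replicate 1 in R821H (0.0256) and R1003Q (0.0247) and without R821H replicate 1 (0.0918). Called lists ranged from 3 to 5, 0 to 5 and 0 to 3 in R1855L, R821H and R1003Q, and called strand ratios from 4 to 14 in R1855L, with 0 in the others. Without WT replicate 2 the camera direction of the let-7 lists turned in R821H, with medians near 0 (-0.00923 for group II and 0.0125 for the family), and without WT replicate 1 they were at -1.36 and -1.34.

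An estimated correlation left 0, 0 and 0 called lists, and p = 0.141 for the 5p difference of 0.279 in R1855L. The depth term gave 5 lists in R821H, a 5p difference of 0.231 in R1003Q, called by camera, 32 strand ratios in R1855L and 1 in R1003Q (miR-590). For the 3p list in R1003Q with that term the camera p was 8.08e-05, and 0.182 with an estimated correlation. Only the 4 libraries gave 4 strand ratios. The smaller fits have fewer samples and no longer share the spread of the other groups, among them the R1003Q pair with its low chi-square. Beyond that, the cause was not tested. Spike-in scaling was not run.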

Other observations

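The tests below were chosen after the fold changes were seen. Of the called R1855L strand ratios toward 5p, 10 had both strands tested, and in all 10 the 3p strand lay further from 0 than the 5p strand. Unlike the ratio, this order depends on library scaling. The margin was small for miR-33b (log2 fold change 0.82 for 5p and -0.90 for 3p) and miR-29a (0.71 and -0.79). Median log2 fold changes were -1.65 for these 3p strands and 0.45 for the 5p strands, a difference in size of 1.20. As a hypothesis, the shift toward 5p may come mainly from loss of the 3p strand; the pairs were selected for their ratio, but not for which strand moved.

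In 38 clusters of hairpins within 10000 bp on 1 strand, the mean absolute difference of R1855L log2 fold changes was 0.782 over 154 pairs, against 0.934 in permuted hairpins (one-sided permutation p = 0.128). The mean runs over pairs, so clusters with many hairpins weigh most. The largest, on chromosome 14, held values from -2.17 (MIR409) to 1.97 (MIR411). Changes of primary transcripts may account for part of the differences, which this test does not decide. MIR222 and MIR221, in the same intron, had mean values of -2.09 and 0.24, and MIR141 and MIR200C had -1.39 and 0.25.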
